A study of Homo sapiens with 31 samples.

How the data were processed

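The series covers PANC-1, an established human pancreatic cancer cell line, with 31 samples. The labels name 3 kinds of experiment: crosslinking libraries that map m6A or the binding of KHSRP (3 miCLIP and 2 PAR-CLIP samples), steady-state RNA-seq of KHSRP knockout cells and of cells labelled NC with a wild-type genotype (3 libraries each), and a series under actinomycin D, which blocks transcription, with 2 libraries per genotype at each of 0, 2, 4, 6 and 8 h. The 5 crosslinking samples were not analysed here. Tables of the other 26 samples were used, and each sample took its genotype, time and replicate number from its label. Knockout is abbreviated KO. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

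Per the labels' protocols, RNA was isolated with TRIzol and RNA-seq libraries were made with a Hieff NGS Ultima Dual-mode mRNA kit; the RNA-seq samples carry the label polyA RNA. STAR, RSEM, Bowtie2, deepTools and the hg19 genome build are named in the submitters' processing notes, without versions, order or roles; the annotation and the use of strand in counting are not given in the sources used here. The steady-state tables have the layout of RSEM gene results: per the file headers, the authors deposited expected counts, TPM and FPKM for 58037 gene identifiers, of which 56993 have a symbol. Expected counts were the basis here; 10.2% of them were not whole and were rounded. Counts of 45 pseudoautosomal copies were added to their partner genes. The actinomycin D tables list 43682 genes: per the file headers, the authors deposited read counts, RPM, RPKM and log2 RPKM, and a molecule signal with its log2 value. The deposited log2 molecule value was an exact straight line of the deposited log2 RPKM within each library, with a slope and an intercept of its own; what set these lines is not given in the sources used here. The 37 mitochondrial genes were at 0 counts in all 20 of these tables. Counts were the basis here, and the molecule scale served as an alternative. Symbols were brought up to date from a reference gene table. In the actinomycin D set 42335 of 43682 names were already current, 408 were changed, and the rest were kept as they were. Coordinates are those of the deposited actinomycin D tables (hg19).

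Total counts were 33706181 to 43278138 per steady-state library and 19177934 to 25768060 per actinomycin D library. Libraries of one group were compared by a chi-square test of their counts over genes with at least 20 counts: chi-square per degree of freedom was 3.81 to 42.8 in the steady-state set and 3.90 to 5.30 in the actinomycin D set, so no pair agreed within sampling noise and all libraries were kept as separate replicates. The largest value, 42.8, was between KO replicates 1 and 2 of the steady-state set. Deviations of same-numbered libraries from their group means correlated at -0.11 to 0.06 across genes in the steady-state set and at -0.05 to 0.03 in the actinomycin D set, so replicate numbers were not treated as pairs.

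Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, and a robust quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. The steady-state fit used the 6 libraries. The 0 h comparison used a fit with one mean per genotype and time over all 20 actinomycin D libraries. Slopes over labelled time, and their difference between genotypes, came from a fit of genotype, time in hours and their interaction over the same 20 libraries. A standard error (SE) is the absolute log2 change divided by the square root of F. Levels are CPM after TMM scaling, as mean ± SD, unless they are called plain CPM. The F test over the 5 labelled times within a genotype was added after the data had been seen.

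Before the data were examined, 27 gene lists, the tests, the alternatives and the rule for named genes were fixed. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01. The fixed list tests were those of the steady state and of the slope difference. The list tests at 0 h were not among them and were added. The lists were integrins, focal adhesion and FAK signalling, extracellular matrix ligands, AU-rich early-response and cytokine transcripts, AU-rich element binding and decay factors, m6A factors, let-7 targets and microRNA machinery, interferon-stimulated genes, antigen presentation, epithelial and mesenchymal genes, G1/S and G2/M genes, p53 targets, integrated stress and unfolded protein response, heat shock, hypoxia and glycolysis, cholesterol synthesis, nuclear oxidative phosphorylation, cytosolic ribosomal proteins, mitochondrially encoded genes, replication-dependent histones, and markers of immune cells, fibroblasts, endothelium, pancreatic acinar and pancreatic endocrine cells. The integrin and FAK lists follow the title of the series and are not independent of these samples. KHSRP, its paralogs FUBP1 and FUBP3, PTK2 (which encodes FAK), MET, ITGAV and ITGB1 were named in every case. For the steady state, genes past the threshold with at least 10 CPM in a group, a proper gene symbol and non-overlapping groups followed, the 10 with the largest change in each direction, with up to 3 called members of each list, or up to 2 members with the smallest p where none was called. The same rule, without the overlap condition, held for slopes, and the 0 h comparison kept the steady-state names. Genes chosen after their values were seen are marked as such.

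Alternatives were RLE scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 50 counts, a replicate block, an added threshold of 1 on the log2 scale, and each library left out in turn. For slopes, scaling to ribosomal protein counts, library size alone, 8 h against 0 h as a factor, and the sets without 8 h or without 0 h were also run. Alternatives chosen after seeing the data, for comparisons and named genes, were offsets that remove a lowess trend (span 0.3) of each library on log2 transcript length, limma on the deposited molecule scale, the ribosomal protein and library size scalings of the 0 h and 8 h comparisons, and fits without the libraries labelled NC 4 h and KO 6 h.

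The tests were tested on simulated negative binomial counts with 200 changed genes. In a simulation of the steady-state comparison, fitted to 16960 genes, 89.6% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold were called. For the 0 h comparison, fitted to 16932 genes, the shares were 71.6%, 94.0% and 100%. For the slope difference with the spread of the slope fit (17114 genes), in which the scatter of labelled times about a line counts as noise, 0% of genes with a 1.5-fold, 8.96% with a 2-fold and 68.2% with a 4-fold difference by 8 h were called. With the spread between replicates alone (16878 genes), these shares were 71.6%, 97.0% and 100%. Simulated libraries were drawn independently, without a deviation shared by the 2 libraries of a labelled time.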

Results

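Messenger RNA was profiled in PANC-1 pancreatic cancer cells in which KHSRP, an RNA-binding protein known to promote the decay of AU-rich transcripts, had been knocked out. The steady-state set held 3 KO and 3 NC libraries of 33706181 to 43278138 counts. The actinomycin D set held 20 libraries of 19177934 to 25768060 counts, 2 for each genotype at 0, 2, 4, 6 and 8 h. The study's design text names the effect of KHSRP on gene expression and on the lifetime of transcripts as its questions.

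KHSRP itself (ENSG00000088247.16, hg19 chromosome 19, 6413113 to 6424822, minus strand) was lower in every KO library than in the NC libraries of its set. In the steady-state set it stood at 10 ± 0.570 CPM in KO and 65.0 ± 0.612 CPM in NC (SD, n = 3 each), a log2 change of -2.70 (SE 0.08, adjusted p = 4.52e-07). Each steady-state KO library still held 370 to 412 KHSRP counts. In the actinomycin D set the plain CPM of KHSRP was 134 to 164 in the 10 libraries labelled KO and 406 to 434 in the 10 labelled NC. Within each set the levels of KHSRP went with the genotype labels. The libraries labelled KO in the actinomycin D set nevertheless held more KHSRP than the steady-state NC libraries, at 62.5 to 63.6 plain CPM. In the actinomycin D set the libraries labelled KO and NC differed in more than KHSRP, as described below. A lower level than in NC therefore does not show a knockout there, and whether KHSRP was lost in those KO libraries was not tested. The tables of the 2 sets were made separately, so levels are not on one scale between them.

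The steady-state comparison asked which transcripts changed in the cells labelled KHSRP knockout. Of the genes named in every case, ITGB1, the common beta integrin subunit, was lower in KO, at 118 ± 25 against 347 ± 38.6 CPM (log2 change -1.56, SE 0.15, adjusted p = 5.66e-05). Also lower were ITGAV, its alpha V partner, at 370 ± 90.0 against 807 ± 13.8 CPM (-1.13, SE 0.14, adjusted p = 0.000229), and MET, the receptor of hepatocyte growth factor, at 74.8 ± 12.1 against 151 ± 6.27 CPM (-1.02, SE 0.11, adjusted p = 0.000105). PTK2, which encodes the focal adhesion kinase FAK, was at 112 ± 11.7 CPM in KO and 115 ± 2.14 CPM in NC, and its log2 change of -0.03 (SE 0.09, adjusted p = 0.766) was within the spread between replicates. Of the KHSRP paralogs, FUBP1 fell by 0.77 on the log2 scale (SE 0.08, adjusted p = 9.93e-05), and FUBP3, at 17.0 ± 2.74 against 18.6 ± 1.40 CPM, did not pass (adjusted p = 0.377). In hg19 ITGB1 lies on chromosome 10 (33189246 to 33247158), ITGAV on chromosome 2 (187454783 to 187545628), MET on chromosome 7 (116312250 to 116438431) and PTK2 on chromosome 8 (141667999 to 142012178).

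After KHSRP, the largest falls among genes of at least 10 CPM were those of SFT2D2 (log2 change -2.30, SE 0.20), TGFBR1, the type I receptor of TGF-beta (-2.28, SE 0.08; 14.9 ± 0.928 against 72.1 ± 2.40 CPM), PGM2L1 (-2.09, SE 0.12), TBC1D8B (-2.08, SE 0.10), the zinc finger genes ZNF780A (-2.04, SE 0.14) and ZNF25 (-2.03, SE 0.16), ZDHHC21 (-2.02, SE 0.14), the scaffold protein gene AKAP12 (-2.02, SE 0.17; 86.9 ± 21.7 against 352 ± 41.6 CPM) and SAMD12 (-1.97, SE 0.13). The largest rises were smaller: LIPG, an endothelial-type lipase, went from 11.8 ± 0.558 to 38.5 ± 3.61 CPM (log2 change 1.71, SE 0.10), followed by H2BC18 (1.66, SE 0.12), PRSS3 (1.51, SE 0.13), PHF7 (1.38, SE 0.10), MVD (1.18, SE 0.09), CHAC1 (1.17, SE 0.10), the mitotic kinase AURKB (1.17, SE 0.08), PPP1R15A (1.14, SE 0.12), KLHDC3 (1.11, SE 0.08) and ARID3B (1.10, SE 0.08). H2BC18 and PRSS3 have close paralogs with which reads could be shared, so their values are uncertain.

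**Figure D1:**
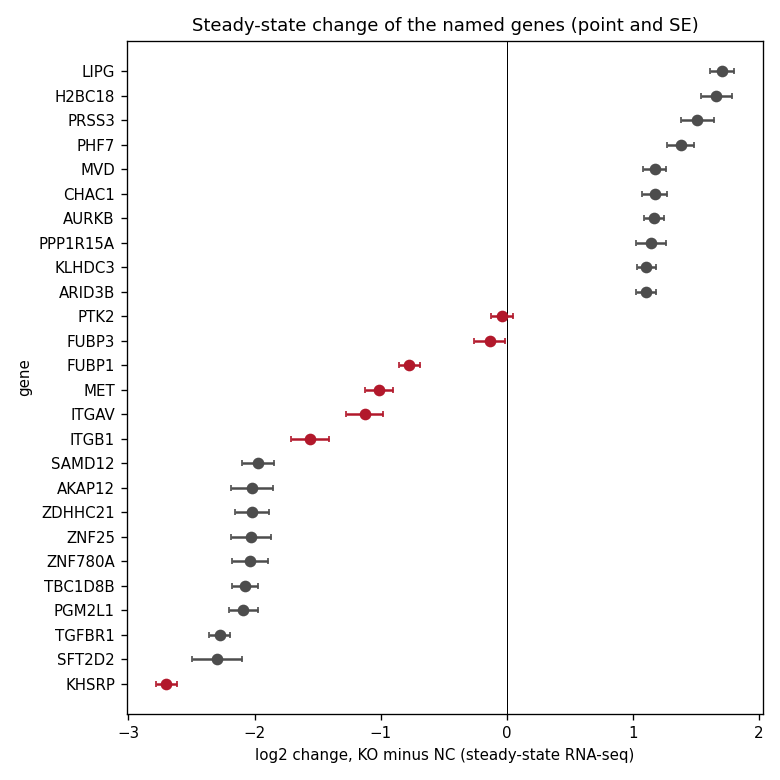
The log2 change of each named gene, KO minus NC, is plotted as a point with its SE (n = 3 libraries per group); red points are the genes named in every case. PTK2 and FUBP3 lie close to 0, ITGB1, ITGAV and MET lie between -1.56 and -1.02, and KHSRP lies lowest at -2.70.

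Across the 17240 genes tested, 4198 were higher and 4528 were lower in KO at an adjusted p under 0.05. Changes of at least 1 on the log2 scale were mostly falls, 1603 against 214 rises. The groups did not overlap in 60.0% of genes, where chance gives 10% for 3 against 3 libraries.

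In cholesterol synthesis, 19 of 23 measured members were higher and 1 was lower in KO (median log2 change 0.69, camera adjusted p = 9.15e-09, and adjusted p = 0.421 with an estimated correlation), among them MVD and LSS (log2 change 1.02, SE 0.08), both enzymes of the pathway. Replication-dependent histone genes, whose transcripts lack a poly(A) tail, were higher for 15 of 16 members (median 0.70, adjusted p = 1.33e-09, and adjusted p = 0.421 with an estimated correlation), such as H3C1 (1.01, SE 0.11); these are near-identical copies, so single members are uncertain. Small structural RNAs without a poly(A) tail (RN7SL1 and 5 others) took 16.0 to 16.4% of counts in NC and 11.8 to 14.7% in KO libraries. It is therefore uncertain how far the libraries, labelled polyA RNA, were selected for poly(A) tails, and what the histone levels reflect. G1/S and DNA replication genes were higher for 16 of 28 members and lower for 2 (median 0.39, adjusted p = 0.000232, and adjusted p = 0.492 with an estimated correlation), with CHAF1A at 0.77 (SE 0.09) and the helicase subunit MCM7 at 0.71 (SE 0.07). G2/M genes were higher for 15 of 30 and lower for 6 (median 0.18, adjusted p = 0.00851, 0.0623 with a replicate block, and adjusted p = 0.495 with an estimated correlation), but not in one direction: AURKB rose while CENPF, a kinetochore protein gene, fell by 1.15 (SE 0.14). Adjusted over the list alone, 20 cholesterol, 15 histone, 20 G1/S and 21 G2/M genes passed. With a correlation estimated from the data none of the lists passed.

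Of the AU-rich element binding and decay factors, 13 of 22 were lower and 3 were higher (median log2 change -0.32, camera adjusted p = 0.00921, adjusted p = 0.495 with an estimated correlation), with TIA1 at -1.59 (SE 0.11) and the exonuclease XRN1 at -1.46 (SE 0.15). Among m6A writers, erasers and readers, 12 of 22 were lower and 3 were higher (median -0.31, adjusted p = 0.0272, adjusted p = 0.495 with an estimated correlation, adjusted p = 0.0923 with length-adjusted offsets), including ZC3H13, part of the methyltransferase complex, at -1.85 (SE 0.19) and the reader YTHDF3 at -1.36 (SE 0.14). The let-7 target and microRNA machinery list was lower for 10 of 20 and higher for 4 (median -0.42, adjusted p = 0.00851, adjusted p = 0.495 with an estimated correlation, adjusted p = 0.273 with length-adjusted offsets), led by TGFBR1 and CDK6 (-1.70, SE 0.10). Mitochondrially encoded genes were lower for 10 of 14 measured members (median -0.68, adjusted p = 0.00851, adjusted p = 0.508 with an estimated correlation), such as MT-ND4 at -1.69 (SE 0.18) and MT-ND4L at -1.71 (SE 0.19). The mitochondrial share of all counts was not lower, at 0.459 to 0.486% in KO and 0.360 to 0.493% in NC libraries. MT-CO1, chosen after its values were seen, was at 4294 ± 93.2 CPM in KO and 4013 ± 597 CPM in NC and did not pass (adjusted p = 0.427). This gene alone made up most of the mitochondrial share, so the share says little about the other members. Adjusted over the list alone, 16 decay factors, 15 m6A factors, 15 let-7 list members and 10 mitochondrial genes passed.

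The lists that follow the title of the study did not pass camera, which sets a list against all other genes. By fry, which tests a list against no change, the integrins passed as lower (adjusted p = 0.0036) and the FAK list did not (adjusted p = 0.0576). In the focal adhesion and FAK list 17 of 46 members were higher and 13 were lower (median 0.05, camera adjusted p = 0.961), with PIK3CA, a catalytic subunit of phosphoinositide 3-kinase, at -1.56 (SE 0.13) and the kinase ROCK2 at -1.42 (SE 0.15). In the integrin list 6 of 14 members were lower and 3 were higher (median -0.48, adjusted p = 0.109), with ITGB1, ITGB8 (-1.28, SE 0.16) and ITGAV falling furthest. Adjusted over the list alone, 30 of the FAK list and 10 of the integrins passed, which is not independent evidence of a direction because both lists came from the title. Transcripts with AU-rich elements, which KHSRP is known to bind, went both ways: 9 of 34 early-response and cytokine transcripts were higher and 9 were lower (median 0.12, adjusted p = 0.622), and the chemokines CCL20 (-2.10, SE 0.14) and CXCL8 (-1.28, SE 0.17) fell. Higher were ATF3 (0.93, SE 0.11), JUN (0.55, SE 0.09) and MYC (0.50, SE 0.09), chosen after their values were seen. Adjusted over the list alone, 18 of these 34 passed. The mean log2 change was -0.07 for the FAK list and -0.04 for the AU-rich list, of the opposite sign to the median and to the camera direction.

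The remaining lists did not pass camera either. Higher and lower members numbered 9 and 5 of 26 extracellular matrix ligands (LAMB3 1.41, SE 0.14), 15 and 6 of 28 hypoxia and glycolysis genes (P4HA1 -1.10, SE 0.09), 13 and 1 of 28 nuclear oxidative phosphorylation genes, 21 and 4 of 73 ribosomal protein genes, 11 and 3 of 24 p53 targets, 9 and 7 of 24 stress and unfolded protein genes, 4 and 2 of 13 heat shock genes, 4 and 3 of 18 antigen presentation genes, 3 and 14 of 30 interferon-stimulated genes, 4 and 6 of 19 epithelial genes (OCLN -0.89, SE 0.11) and 6 and 8 of 23 mesenchymal genes (ZEB1 -1.71, SE 0.14). Their adjusted p ranged from 0.109 to 0.976. By fry, the extracellular matrix, hypoxia, oxidative phosphorylation and p53 lists passed as higher and the interferon list as lower (adjusted p 0.00981 to 0.0239). Adjusted over the list alone, in the same order, 14, 21, 14, 13, 14, 16, 5, 7, 17, 10 and 15 members passed. Median and mean differed in sign for the antigen presentation (0.03 and -0.10), heat shock (-0.10 and 0.02, camera direction up) and mesenchymal lists (0.13 and -0.11). Of markers of other cell types, 3 endothelial, 3 immune, 1 endocrine, 0 acinar and 4 fibroblast genes passed the count filter, too few for a set test. Of the fibroblast markers 3 were higher and 1 was lower, and PDGFRB stood at 2.07 ± 0.179 CPM in KO against 1.04 ± 0.194 in NC.

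Longer transcripts were lower in KO. Across the 17240 genes, the log2 change correlated with transcript length at a Spearman rho of -0.24; genes are not independent replicates. In the 4310 genes with transcripts of 134 to 1348 bases, 1083 were higher and 528 were lower, and in the 4310 genes of 3312 bases or more 748 were higher and 2019 were lower. After length-adjusted offsets, 4475 genes were higher and 4173 lower; ITGB1 stood at -1.49 (adjusted p = 1.24e-05), ITGAV at -0.68 (adjusted p = 0.000374) and MET at -0.65 (adjusted p = 0.00011). The let-7 and m6A lists no longer passed, and the extracellular matrix list did (higher in KO, adjusted p = 0.00344). KO replicate 1 lay closest to NC in its length trend.

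**Figure D2:**
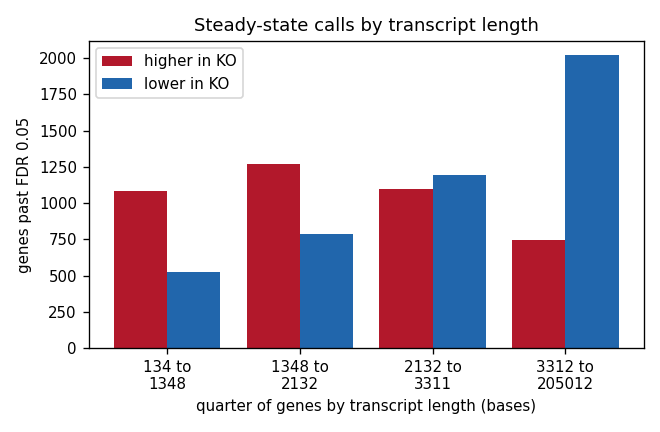
Bars give the number of genes past an adjusted p of 0.05 in the steady-state comparison, for 4 equal groups of genes by transcript length in bases. Falls outnumber rises, 2019 to 748, among the longest transcripts, and rises outnumber falls, 1083 to 528, among the shortest.

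The libraries labelled KO and NC were also compared at 0 h of the actinomycin D set, before transcription was blocked according to the labels. The genotypes of this set differed in more than KHSRP, so the differences below are between the labels and are not put down to KHSRP. Here ITGAV and ITGB1 were higher in the libraries labelled KO: ITGAV at 733 ± 19.8 against 252 ± 7.01 CPM (SD, n = 2 each; log2 change 1.54, SE 0.04, adjusted p = 9.6e-31) and ITGB1 at 2319 ± 99.7 against 1434 ± 24.7 CPM (0.69, SE 0.03, adjusted p = 4.43e-22). PTK2 was also higher, at 152 ± 0.548 against 93.7 ± 2.81 CPM (0.70, SE 0.06), while MET was lower (-0.85, SE 0.05; -0.01 on the deposited molecule scale, where it did not pass), as were FUBP3 (-1.26, SE 0.05) and TGFBR1 (-1.40, SE 0.07). On the molecule scale the log2 change was 2.60 for ITGAV, 1.75 for ITGB1, 1.64 for PTK2, -0.45 for FUBP3 and -0.64 for TGFBR1. FUBP1 did not pass (-0.07, SE 0.05, adjusted p = 0.194), but it passed as higher in KO with counts scaled to ribosomal protein genes (0.38) and on the molecule scale (0.84). AKAP12 stood at 1271 ± 33.0 CPM in the libraries labelled KO and 41.8 ± 4.73 CPM in those labelled NC, and ZNF780A at 156 ± 9.78 and 12.7 ± 0.542 CPM, both opposite to the steady state. LIPG had 0 counts in both NC libraries and 36.2 ± 1.37 CPM in KO.

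**Figure D3:**
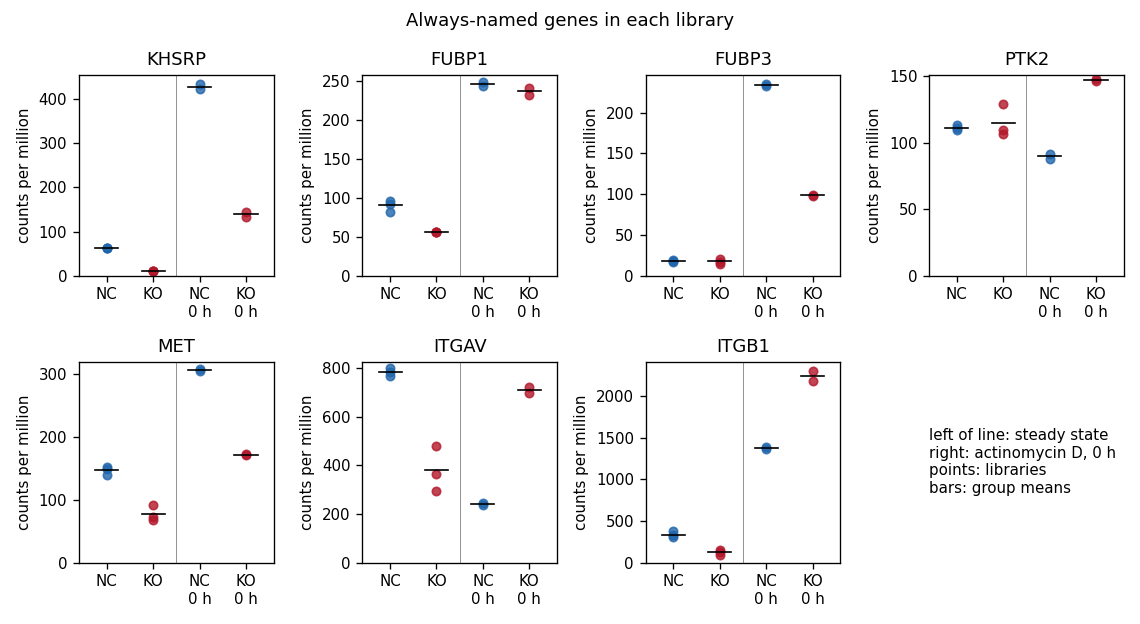
Each point is the plain CPM of one library for the genes named in every case, with bars at the group means; the left part of each panel holds the steady-state libraries (n = 3 per group) and the right part those at 0 h of actinomycin D (n = 2 per group). KHSRP and MET are lower in KO in both sets, whereas ITGAV and ITGB1 are lower in KO in the steady state and higher in KO at 0 h; the fall of MET at 0 h did not pass on the deposited molecule scale.

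Integrin genes were higher as a set in the libraries labelled KO at 0 h, 14 of 16 members against 1 lower (median log2 change 2.93, camera adjusted p = 4.28e-11, adjusted p = 0.000767 with an estimated correlation); this list followed the title of the study. Also higher were interferon-stimulated genes (22 of 33, adjusted p = 0.00481 and 0.0216 with an estimated correlation), AU-rich early-response transcripts (19 of 35, adjusted p = 0.00926 and 0.0263) and mesenchymal genes (13 of 25 with 11 lower, adjusted p = 0.00234 and 0.0216). Early-response transcripts also differed widely between the labelled times (below), so their result depends on the 0 h labels being right. Cholesterol synthesis genes were lower, 15 of 24 (median -0.68, adjusted p = 0.000526 and 0.0154 with an estimated correlation), as were ribosomal protein genes, 63 of 73 (median -0.56, adjusted p = 2.61e-10, and adjusted p = 0.0736 with an estimated correlation). Lower too were 17 of 28 G1/S genes (median -0.34, adjusted p = 0.0104, and adjusted p = 0.0884 with an estimated correlation) and 16 of 28 nuclear oxidative phosphorylation genes (median -0.38, adjusted p = 0.0126, and adjusted p = 0.103 with an estimated correlation). The stress and unfolded protein list passed as lower (adjusted p = 0.0183, and adjusted p = 0.0694 with an estimated correlation) with 10 members each way and a median of 0.18. Adjusted over the list alone, 15 integrins, 28 interferon-stimulated, 28 early-response, 24 mesenchymal, 20 cholesterol, 68 ribosomal protein, 23 G1/S, 21 oxidative phosphorylation and 20 stress genes passed. These falls are relative to the total: on the deposited molecule scale the medians were 0.18 for cholesterol, 0.39 for ribosomal protein, 0.52 for G1/S and 0.54 for oxidative phosphorylation genes. Scaled to ribosomal protein genes the G1/S and oxidative phosphorylation medians were 0.11 and 0.07. The integrin median was 3.98 on the molecule scale. In all, 6287 genes were higher and 5600 lower of 17715 tested. With counts scaled to ribosomal protein genes, where the median gene was 0.50 higher in KO on the log2 scale, the split was 8807 to 3517. On the deposited molecule scale, where the median gene was 0.90 higher in KO on the log2 scale, it was 10149 to 2284.

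The genotypes of the actinomycin D set also differed in genes that were on in every library of one and off in every library of the other. With on set at 20 plain CPM or more and off below 0.5, 48 genes were on in all 10 libraries labelled NC and off in all 10 labelled KO, and 61 genes the other way. The steady-state set had 0 and 0 such genes. The tumour suppressor CDKN2A, which PANC-1 cells are known to have lost by deletion, had 2728 to 5476 counts in each of the 10 libraries labelled NC, 0 in each of the 10 labelled KO, and at most 6 in a steady-state library. The keratin gene KRT19 was at 368 to 467 plain CPM in the libraries labelled KO and 293 to 366 in all 6 steady-state libraries, but at 0.646 or less in those labelled NC. CDKN2A and KRT19 were chosen after their values were seen.

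The log2 changes of the steady state and of 0 h were unrelated across genes. Over the 14286 genes tested in both, Pearson's r was -0.03 and Spearman's rho -0.05; genes are not independent replicates. Of the steady-state calls, 1531 genes were higher in both comparisons, against 1570 for independent lists, and 1147 were lower in both, against 1243. Of 5932 genes called in both, 45.1% had the same sign. Absolute changes above 3 on the log2 scale numbered 8 in the steady state and 1712 at 0 h.

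The decay comparison asked whether transcripts were lost at different rates in the libraries labelled KO and NC, which differed in more than KHSRP. No gene passed for a slope over the labelled times in NC, in KO or for their difference by edgeR, where 403, 635 and 529 of 17715 genes had an unadjusted p under 0.05. These were 2.27%, 3.58% and 2.99% of genes, below the share of 0.05 that chance alone gives, so they are no sign of slopes. DESeq2 called 2, 10 and 6, and limma-voom 0, 0 and 0. Without the 8 h libraries edgeR called 2774 genes for a slope in KO, 2267 of them rising and 507 falling. On the deposited molecule scale, where the median slope was -0.15 per hour in NC and -0.17 in KO (log2), 7536 genes fell over time in NC and 8636 in KO, and the slope difference still gave 0 genes. The slope differences (KO minus NC, log2 per hour) were 0.00 (SE 0.02) for KHSRP, -0.02 (SE 0.04) for ITGAV, -0.04 (SE 0.05) for ITGB1, -0.01 (SE 0.02) for MET and -0.02 (SE 0.02) for PTK2, with an adjusted p of 1 for each. In the extracellular matrix list, the laminin gene LAMA3 had a slope difference of -0.12 (SE 0.03, edgeR adjusted p = 0.993), and it alone of that list passed when adjusted over the list alone.

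Ribosomal protein genes (73 members, median slope difference -0.03 per hour, camera adjusted p = 8.4e-07), nuclear oxidative phosphorylation genes (28, median -0.02, adjusted p = 0.0205), G2/M genes (30, median -0.02, adjusted p = 0.0205) and extracellular matrix ligands (26, median -0.02, adjusted p = 0.0392) had lower slopes in KO as sets. With an estimated correlation, which was 0.97 for the ribosomal protein genes, the adjusted p was 0.753 for each of these 4. Without the libraries labelled NC 4 h and KO 6 h only 1 list passed, and leaving out single libraries gave 0 to 7. From 0 h to 8 h the ribosomal protein median rose more in KO (0.27) than in NC (0.15), opposite to the slopes. The same held for oxidative phosphorylation genes (0.24 and 0.10). G2/M medians were -0.40 in KO and 0.03 in NC, and extracellular matrix medians 0.06 and 0.07. Ribosomal protein levels were lowest at the labels NC 4 h (median log2 CPM 8.83) and KO 6 h (8.14). AU-rich early-response transcripts had a median slope difference of 0.11 (adjusted p = 0.0903), and integrins of -0.03 (adjusted p = 0.135). In all 20 lists that did not pass, these included, the adjusted p was 0.078 or more. For genes called in the steady state, the median slope difference was -0.002 for genes lower in KO and -0.005 for genes higher in KO, a difference of 0.003. Neither set passed camera at an unadjusted p of 0.05, but genes higher in KO did with counts scaled to ribosomal protein genes, and genes lower in KO did without NC 8 h replicate 2.

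Levels relative to the total did differ between the labelled times, but not in order of time. Short-lived transcripts were highest in the libraries labelled NC 4 h and KO 6 h. MYC was at 25.8 ± 0.610 CPM at 0 h, 296 ± 14.1 at 4 h and 23.7 ± 0.999 at 8 h in NC (SD, n = 2 each), and at 7.44 ± 0.807, 69.1 ± 3.14 and 8.79 ± 1.21 CPM at 0, 6 and 8 h in KO. FOS was at 6.80 ± 0.590 CPM at 0 h and 527 ± 15.2 at 4 h in NC, and at 0.841 ± 0.430 CPM at 0 h and 65.6 ± 0.272 at 6 h in KO. MCL1, whose transcript is also known to turn over fast, was at 115 ± 3.16 and 370 ± 0.959 CPM in NC at 0 and 4 h. Of 35 AU-rich early-response transcripts, 27 differed between labelled times in NC and 25 of these were highest at 4 h, and 28 differed in KO, of which 20 were highest at 6 h. MYC, FOS and MCL1 were chosen after their values were seen.

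**Figure D4:**
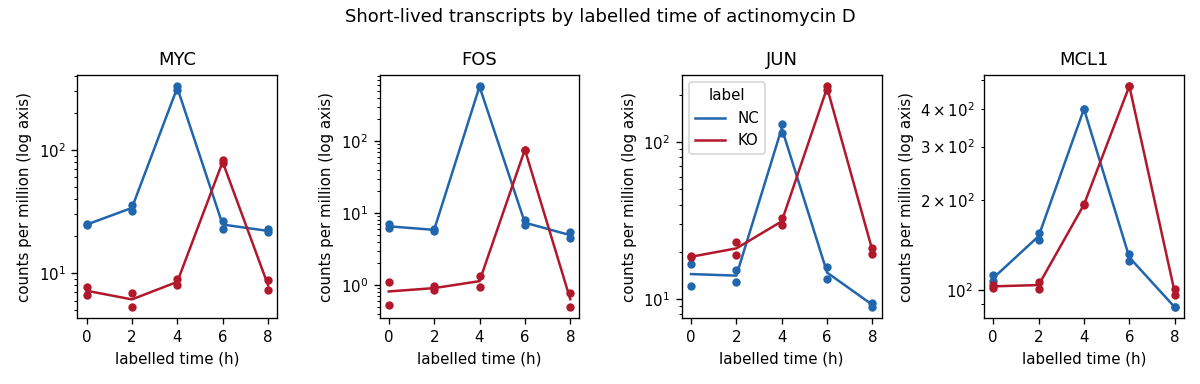
Plain CPM of 4 short-lived transcripts in each actinomycin D library (points, n = 2 per genotype and time) against the labelled time in hours, on log axes, with lines through the means. All 4 transcripts are highest at 4 h in the libraries labelled NC and at 6 h in those labelled KO, and none falls steadily from 0 to 8 h.

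Over all genes, 9683 of 17715 differed between labelled times in NC and 9902 in KO. Of these, 4519 were highest at 4 h in NC and 3662 at 6 h in KO, 3209 and 3475 at 8 h, and 898 and 729 at 0 h. Between 8 h and 0 h, 286 genes rose and 282 fell in NC, and 2004 rose and 1903 fell in KO, relative to the total. Ribosomal protein genes, known for stable transcripts, rose for 36 of 73 members in NC (median log2 change 0.15) and for 57 in KO (median 0.27). Nuclear oxidative phosphorylation genes rose for 4 of 28 in NC and for 22 of 28 in KO. In KO, 23 of 30 G2/M genes fell (median -0.40), whereas in NC 1 fell and 3 rose (median 0.03). The rises hold only relative to the total. With counts scaled to ribosomal protein genes, where the median gene changed by -0.13 in NC and -0.22 in KO, 5 oxidative phosphorylation genes rose and 2 fell in KO, and 28 G2/M genes fell. On the deposited molecule scale 72 ribosomal protein genes fell in NC and 73 in KO, and 28 oxidative phosphorylation genes fell in KO, as did 30 G2/M genes. Over all genes on that scale, with a median change of -1.17 in NC and -1.77 in KO, nearly all calls were falls, 11777 and 13473.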

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

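The tests of the on and off genes, of the spread of the length trend between libraries, and of short AU-rich transcripts were chosen after those results had been seen; the zinc finger and molecule scale tests, the test of ITGB1, ITGAV and MET after length adjustment, and the counts over other splits were fixed before theirs.

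Of 20 named genes that passed the threshold in both sets, 10 had the same sign and 10 had opposite signs, the latter with every KO library on the other side of every NC library; the difference between the sets was not tested. At 0 h the log2 change, KO minus NC, was 1.54 for ITGAV and 0.69 for ITGB1, against -1.13 and -1.56 in the steady state. It was 4.93 for AKAP12, 3.62 for ZNF780A, 1.61 for SAMD12, 1.52 for ZNF25 and 1.42 for TBC1D8B, all lower in KO in the steady state. It was -0.68 for MVD, -1.2 for PPP1R15A and -0.76 for KLHDC3, all higher in KO in the steady state; on the deposited molecule scale MVD (0.15) and KLHDC3 (0.09) did not pass, nor did MVD scaled to ribosomal protein genes (-0.23). Of the lists, cholesterol synthesis (median -0.676 at 0 h, 0.693 in the steady state) and G1/S and DNA replication (median -0.34 at 0 h, 0.388 in the steady state) passed camera with opposite directions relative to the total. With an estimated correlation neither passed in the steady state (camera adjusted p = 0.421 and 0.492). At 0 h cholesterol synthesis then still passed (adjusted p = 0.0154) and G1/S did not (adjusted p = 0.0884). On the molecule scale their 0 h medians were 0.176 and 0.517. In a test of the interaction, 1169 genes differed between the genotypes in their change from 0 h to 8 h, 507 with a higher and 662 with a lower change in KO; scaled to ribosomal protein genes these were 148 and 1048, and on the molecule scale 34 and 6672.

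The pattern of on and off genes argues against a comparison of one cell line with and without KHSRP in the actinomycin D set. Of the 48 genes on in the libraries labelled NC and off in those labelled KO, 93.8% were off in all 6 steady-state libraries, and 100% of the 61 genes on only in the libraries labelled KO were detected in all 6; this is consistent with the libraries labelled NC coming from another cell line, a hypothesis that the labels do not record. Loss of KHSRP would need the 48 genes in steady-state NC cells, where only 2.08% reached 1 CPM. Depth was even, with a ratio of mean totals of 0.964 between the genotypes. For these on and off genes the libraries labelled KO mostly resembled the steady-state libraries. Which line the libraries labelled NC may be, and whether those labelled KO match the steady-state cells in other genes, were not tested.

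For the peaks at the labels NC 4 h and KO 6 h, if early-response genes alone had been induced during treatment, zinc finger genes, which are not part of that response, would not be highest at the same labels. Their median log2 CPM (424 genes) was 1.38 higher at 4 h than at 0 h in NC and 1.13 higher at 6 h than at 0 h in KO, the highest of the 5 times in both, and 86.6% and 87.3% of them were higher. Scaling does not account for it, since the early-response list was also higher on the deposited molecule scale, by 2.04 in NC and 2.44 in KO. Wrong time labels on some libraries may explain these levels, but no sample was moved to another time. Handling of the cultures stays open and untested. The total deposited molecule signal, in one unit throughout, was 162 and 148 in the libraries labelled KO 0 h. It was 86.1 and 80.9 at KO 6 h and 40.3 and 41.8 at KO 8 h. For KO 6 h this order goes with the label and not with a true time of 0 h. At NC 4 h the total was 86.6 and 78.8, close to NC 0 h (85.6 and 82.6), which leaves a wrong label open there. What set this signal is not given, so these totals do not decide the question. Whether the labels account for the lack of slope calls stays open: edgeR called no slope without the libraries labelled NC 4 h and KO 6 h either, which leaves the other labels untested, and 2774 genes in KO without the 8 h libraries.

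The fall of long transcripts in the steady-state KO libraries is the last pattern. The slope of a library's log2 level on log2 length differed within a group by up to 43.4% of the difference between KO and NC, which leaves open a length bias of the libraries. After length adjustment ITGB1, ITGAV and MET, all 3 genes tested, stayed lower and past the threshold. The average length trend is therefore not the whole of their fall. Their unadjusted falls were each larger than the median change of -0.308 among genes of 3312 bases or more, so this outcome was likely beforehand. The adjustment removes only the average trend, so a length bias that acts more strongly on single genes stays open for these 3. Among AU-rich transcripts of at most the median length (20 genes), the median change was 0.0565. A length bias and the loss of KHSRP cannot be told apart for the trend, since both follow the same 3 against 3 libraries.

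Other splits of the 6 steady-state libraries into 3 and 3 gave at most 0 genes, against 8726, and at most 5 lists, against 8. In each case 1 of the 10 splits, the real one, was as large, and 10 splits are too few for a share under 0.05. Every other split mixes the genotypes and so adds their difference to the spread, which by itself lowers the calls. These counts therefore decide nothing about chance. For the slope difference, the genotype was exchanged between libraries of the same labelled time in 100 drawn splits, the real one included. Such an exchange carries the difference between the genotypes into the slopes, so the shares of splits decide nothing about chance. For the genes (0) all 100 splits were at least as large, by construction, with 7730 in the highest other. For the lists (4) 36 were as large, with 8 in the highest other, and for the slope difference of steady-state calls (0.00279) 77 were, with 0.0375 in the highest other.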

How the results depend on the processing

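Offsets for transcript length, the deposited molecule scale, fits without the libraries labelled NC 4 h and KO 6 h, ribosomal protein or library size scaling at 0 h and 8 h, and the tests over any labelled time were chosen after seeing the data. Under the alternatives, 241 values for the comparisons were classed as the same, 37 as moved and 5 changed sign. For counts, the same meant within 1.5 times. For Pearson's r it meant within the SD of the values with single steady-state libraries left out. For the slope difference of steady-state calls it meant only that the camera p of the lower genes stayed on its side of 0.05, so the value itself could change more. Of the values for named genes 881 kept direction and side, 24 kept only the direction, 9 of genes not called changed sign and 3 of called genes changed sign. The last 3 were at 0 h on the molecule scale: MVD (0.151), KLHDC3 (0.088) and SFT2D2 (0.35), none past the threshold there. FUBP1, PGM2L1 and ZDHHC21, not called at 0 h, passed as higher in KO on that scale (0.836, 0.696 and 0.751) and scaled to ribosomal protein genes (0.381, 0.313 and 0.397). Unless stated, the cause was not tested. An added threshold of 1 on the log2 scale left 1817 steady-state genes and 6621 genes at 0 h, by its construction. Leaving out single libraries gave 6723 to 10150 and 10779 to 11939 genes. For slopes in NC, in KO and for their difference, edgeR called 0 genes each, DESeq2 2, 10 and 6, and 8 h against 0 h 568, 3907 and 1169; the molecule scale gave 7549 in NC and 8644 in KO, and KO without the 8 h libraries gave 2774. Leaving out single libraries gave 0 to 2 genes for the difference and in NC, highest without NC 8 h replicate 1, and 0 to 1 in KO; 1 gene passed for the difference without KO 0 h replicate 2 or KO 4 h replicate 1, and in KO without these, KO 4 h replicate 2, KO 6 h replicate 1 or KO 8 h replicate 2. Lists past the threshold in the steady state numbered 8, with an estimated correlation 0 and with fry 14. For the slope difference, 4 lists became 0 with an estimated correlation, 0 with fry, 1 without the libraries labelled NC 4 h and KO 6 h, and 0 to 7 with single libraries left out, lowest without NC 8 h replicate 2 and highest without NC 0 h replicate 2; 2 lists passed without KO 0 h replicate 2 or either replicate of KO 2 h or KO 6 h. Pearson's r between the steady state and 0 h was -0.0453 with a stricter filter, -0.0479 over steady-state calls, -0.0215 with length-adjusted offsets and -0.0416 (without steady-state NC replicate 1) to -0.0243 (without NC 0 h replicate 2) with single libraries left out. The slope difference of steady-state calls, 0.00279, changed sign for calls of at least 1 on the log2 scale (-0.0312), without the libraries labelled NC 4 h and KO 6 h (-0.00471), and without KO 6 h replicate 1 (-0.0011), NC 8 h replicate 1 (-0.000257) or NC 8 h replicate 2 (-0.0072). Leaving out single libraries gave -0.0072 to 0.0146, and leaving out all 0 h libraries 0.0294. Without the libraries labelled NC 4 h and KO 6 h, genes that differed between labelled times numbered 6759 in NC and 7192 in KO.

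Replicate numbers did not pair the libraries: deviations of same-numbered steady-state libraries correlated at -0.11 to 0.059, and 1 of 3 KO libraries correlated best with its own number. A replicate block gave 8706 steady-state genes, against 8726, and 7 lists, against 8, with G2/M lost. The slope fit could miss most 2-fold and some 4-fold differences by 8 h, so the lack of slope calls leaves such differences open. With its spread, simulated differences of these sizes were called for 8.96% and 68.2% of genes. With the spread between replicates alone they were called for 97.0% and 100%. In the data the 2 libraries of a label deviated together, such as MYC at NC 4 h (331 and 308 plain CPM). The simulated libraries did not, so these shares are only a rough guide.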

Other observations

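Some of the genes on or off between the genotypes of the actinomycin D set follow, chosen after their values were seen. In plain CPM, the folate receptor gene FOLR1 averaged 988 in the libraries labelled NC, the fibrillin gene FBN2 494, the intestinal phosphatase gene ALPI 453 and the lipase gene LPL 445, while each averaged under 0.5 in the libraries labelled KO and in both steady-state groups. In the other direction, the kinesin gene KIF1A averaged 324, the elongase gene ELOVL2 224 and the secreted protein gene AGR2 176 in the libraries labelled KO. These 3 genes averaged 51.6, 94.8 and 222 in steady-state NC and 68.0, 101 and 204 in steady-state KO. The ribosomal protein gene RPS16, which is not one of the on and off genes, stood at 741 ± 12.7 CPM in NC and 6301 ± 197 CPM in KO at 0 h (SD, n = 2 each). It went against its list, of which 63 of 73 members were lower and 5 were higher in KO at 0 h.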
